A study of Mus musculus with 4 samples.

How the data were processed

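The values were the probe set signals deposited with the 4 arrays, in the unit intensity on a linear scale. They were taken as the authors deposited them, and the algorithm and software that produced them are not given in the sources used here. The 2% trimmed mean was 500.15 to 500.20 on the arrays, so a scaling to a common trimmed mean had been done before deposit. No raw files were analysed here, and no detection calls were available.

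Of 22690 probe sets, 64 were controls and 22626 were not. Of the non-control probe sets, 20380 had exactly 1 gene symbol, 691 had several and 1555 had none, and 13 control probe sets with a symbol were not used. The 20380 covered 12393 genes, of which 4956 had several probe sets. Each gene was represented by its probe set with the highest mean. Values were transformed as log2(signal + 16) and each array was centred on its median over the non-control probe sets, then set back to the mean of the 4 medians. The median signal before centring was 163.1 on the WT placebo, 163.0 on the WT RU486, 188.4 on the PAX8PPARg placebo and 170.3 on the PAX8PPARg RU486 array. Genes with a mean at or above the median of all genes were kept for counts and fits, which left 6197.

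The comparisons were RU486 minus placebo in each genotype, PAX8PPARg minus WT under each treatment, and the difference of the RU486 effect between genotypes. With 1 array per group these have no test, and genes were counted by size alone, at 2-fold and 8-fold. Additive models with genotype and treatment over the 4 arrays were fitted with limma, with moderated statistics and Benjamini-Hochberg adjustment at 0.05. They had 1 residual degree of freedom. The diagonal split of the arrays, which is the contrast of the interaction, was fitted in the same way with either factor as the covariate.

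A total of 35 gene lists were written for cell types, hormone and signalling targets, tissues that lie near a tumour, and technical gene sets. For each list the median difference over its measured genes, without the level filter, was compared with 10000 random lists of the same size drawn from the same 20 bins of mean level. A list stood apart at or below percentile 1 or at or above percentile 99. The percentile concerns genes, which are not independent, and says nothing on the spread between mice. A signal was called within the background range when it did not exceed the highest of 27 bacterial control probe sets on its array.

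The comparisons, the transformation, the filter, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 genes with the largest positive and the 12 with the largest negative difference for RU486 in each genotype and for genotype under placebo, 8 and 8 for genotype under RU486, and 6 and 6 for the double difference. It added the receptor genes, and the 4 members of each list apart with the largest difference in the list's direction. The text prints some of those 4 members, and predicted genes are given by count. Genes from the limma fits, genes that differed in both genotypes, and the genes in the signal plot were picked after their values were seen, as was the scaling of the lists without centring.

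Simulated data were put through the same steps. With noise of SD 0.185 log2, taken from the spread between probe sets of a gene, limma recovered 198 of 200 genes changed by 1 log2, with 9 false calls. It recovered 200 of 200 at 2 log2 with 0 false calls and 200 of 200 at 3 log2 with 6 false calls. Noise between mice and between pools is unknown and was not simulated. The simulated effect was the same in both genotypes. In the real data the difference of the RU486 effect between genotypes had an SD of 1.17 log2 over genes, and it enters the residual of the additive fits. The recovery therefore does not give the power of those fits on the real arrays. Of 200 random lists of 18 genes, 1 stood apart with no shift, 71 with a shift of 0.5 log2 and 189 with a shift of 1 log2. Python 3.11.15, numpy 2.4.6, R 4.3.3 and limma 3.58.1 were used.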

Results

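Mammary tumours were induced in female mice by the progestin MP (Depo-Provera, 15 mg) followed by 4 weekly oral doses of 1 mg DMBA, a polycyclic hydrocarbon carcinogen. The mice were wild-type FVB (WT) or carried MMTV-PAX8PPARg, a transgene that places a fusion of the transcription factor PAX8 and the nuclear receptor PPARg under the mouse mammary tumour virus promoter, which is active in mammary epithelium. Pellets with a 60-day release held placebo or 2.5 mg RU486 (mifepristone), an antagonist of the progesterone and glucocorticoid receptors. The first pellet went in on the day after the last DMBA dose, and a second was given after 60 days. Each of the 4 groups had 1 Affymetrix array, hybridised with RNA pooled in equal amounts from 5 mice. The spread between mice and between pools is therefore unknown, no comparison of single arrays has a test, and the number of arrays limits the precision of every value below. Differences are on the scale of log2(signal + 16), with each array centred on its median, and are taken as the first-named group minus the second.

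The arrays had the same trimmed mean signal (500.2 on the WT placebo array) but differed in other respects. The 18 spike-in control probe sets were 1.58 times as bright on the WT RU486 array and 2.44 times as bright on the PAX8PPARg RU486 array as on the WT placebo array, and 1.01 times as bright on the PAX8PPARg placebo array. Bacterial control probe sets, which match no mouse transcript, reached at most 9.6, 18.5, 8.3 and 35.3 on the WT placebo, WT RU486, PAX8PPARg placebo and PAX8PPARg RU486 arrays. A signal under that level on its array is called within the background range, and a difference or rank that rests on it is not exact. The ratio of 3' to 5' Gapdh probe sets, a measure of RNA integrity, was 2.51, 3.33, 2.89 and 3.01 in the same order, and that of Actb was 1.15, 1.03, 1.05 and 1.32, so the order of the arrays differed between the 2 genes. Across probe sets, the WT placebo array correlated most closely with the PAX8PPARg RU486 array (Pearson r = 0.960) and the WT RU486 array least closely with the PAX8PPARg RU486 array (r = 0.917). Probe sets are not independent replicates.

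The parts of the transgene and the hormone receptors were read first, with every probe set. The Pax8 probe set was within the background range on all 4 arrays, with signals of 0.5 on the WT placebo array, 1.8 on the WT RU486 array, 0.4 on the PAX8PPARg placebo array and 3.1 on the PAX8PPARg RU486 array. The Pparg probe set read 75.9, 35.4, 497.5 and 13.2 in that order, the last within the background range. Whether either probe set detects the transcript of the fusion is not given in the sources used here, so these values check neither the transgene nor the labels. Pgr, the progesterone receptor, read 37.3, 37.9, 235.8 and 78.0, and Esr1, the estrogen receptor, read 105.6, 78.3, 363 and 2.3, the last within the background range. The 3 probe sets of Nr3c1, the glucocorticoid receptor, differed by 0.19, -0.09 and 0.26 log2 between RU486 and placebo in WT, and by -0.59, -0.70 and -0.24 in PAX8PPARg.

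The first comparison asked how tumours of WT mice differed between RU486 and placebo. Epithelial genes were far lower in the RU486 pool, while macrophage genes were higher. Of 18 luminal epithelial genes, 16 were at least 2-fold lower, with a median difference of -3.27 log2. The cytokeratin gene Krt7 had signals of 3687 under placebo and 112 under RU486, the tight junction gene Cldn7 1443 and 43.5, and the epithelial splicing regulator Esrp1 1517 and 66.5. Of 21 macrophage and monocyte genes, 20 were at least 2-fold higher, with a median of 1.79, among them the chemokine receptor gene Cx3cr1 (3.51), the complement gene C1qa (2.68), the Fc receptor gene Fcgr1 (2.74) and Apoe (2.67).

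Other epithelial programmes followed the same direction in WT. Milk protein genes were lower, with 14 of 15 at least 2-fold lower and a median of -5.03. Wap, the whey acidic protein gene, had signals of 9419 under placebo and 159 under RU486, and the lactalbumin gene Lalba had 2456 and 19.0. The lipase gene Cel read 3300 under placebo and 6.8, within the background range, under RU486. Basal and myoepithelial genes had a median of -1.94, with 13 of 17 at least 2-fold lower, including Krt5 (-3.14), the laminin gene Lama3 (-3.57) and Krt14 (-4.76), whose 3 probe sets ranged from -4.76 to -0.14 and had a mean of -3.15. Squamous and keratinized genes had a median of -2.02, and 18 of 22 were at least 2-fold lower. That median lies between Ivl and Sprr2h, both within the background range on the WT RU486 array (8.0 and 6.7), so its size is not exact. Krt6a, Krt16, Krtdap and Krt1 were all within the background range on the WT RU486 array, at signals of 9.7, 3.6, 13.2 and 1.3, against 1308, 778, 771 and 352 under placebo. Hair and hair follicle genes also stood lower (median -1.99, 16 of 19 at least 2-fold lower), with the inner root sheath genes Krt27 at -4.48 and Tchh at -3.65.

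Genes linked to progesterone signalling had a median of -1.13 in WT, with 7 of 13 at least 2-fold lower and 0 at least 2-fold higher. They included Elf5, a transcription factor of alveolar cells (-5.89), Stat5a, which relays prolactin signals (-2.59), Id4 (-2.12), and Tnfsf11, the gene of RANKL (-2.49, and -0.65 for its second probe set). Among the 6 that stayed within 2-fold were Pgr (0.02) and Ccnd1 (0.93). The luminal list had a median of -3.27 on the same arrays, so lower progesterone signalling cannot be told from the general fall of epithelial genes. Adipocyte genes had a median of -1.01, led by the glycerol phosphate dehydrogenase gene Gpd1 (-2.63, and -1.30 as the mean of its 4 probe sets), the lipoprotein lipase gene Lpl (-2.11) and the resistin gene Retn (-1.53). Targets of PPARd and PPARa in fatty acid oxidation had a median of -0.86, with Fabp3 at -4.20. The Notch list, which holds ligands and receptors beside targets, had a median of -1.15, with the ligand gene Dll1 at -1.87 and the receptor gene Notch3 at -1.73. Its target genes Hes1, Hey1, Hey2, Heyl, Nrarp and Dtx1 differed by 0.56, -1.17, -0.39, -1.15, -1.39 and -2.29. Dtx1 was within the background range under RU486. Neutrophil and myeloid granule genes had a median of -0.78, led by Ltf (-4.02), Lcn2 (-3.21), Cxcl5 (-3.12) and S100a9 (-2.68), of which Ltf and Lcn2 are also made by mammary epithelium. Stem and progenitor genes (median -0.48) included Prom1 (-2.87) and Kit (-2.26). Wnt targets (median -0.47) included Wif1 (-4.53) and Axin2 (-0.88). Of 16 Wnt targets, 3 were at least 2-fold lower and 2 at least 2-fold higher, Dkk2 (3.55) and Notum (1.49).

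Higher in the WT RU486 pool, besides macrophage genes, were genes of antigen presentation by MHC class II (median 1.15, 6 of 10 at least 2-fold higher), mesenchymal genes (0.91, 8 of 20), mast cell genes (0.91, 5 of 11), B and plasma cell genes (0.80, 6 of 13) and AP-1 and immediate early genes (0.64, 4 of 19). Named members were the dendritic cell maturation gene Cd83 (3.11), the invariant chain gene Cd74 (1.22), Zeb2, a repressor of E-cadherin (2.60), S100a4 (1.82), the fibronectin gene Fn1 (1.39), the tryptase genes Tpsab1 (3.44) and Tpsb2 (2.51), and Fosl1 (1.87). Ighm, an immunoglobulin heavy chain gene, differed by 3.35, but its 11 probe sets ranged from -0.47 to 3.93. Blk, which counts among the 6 B and plasma cell genes at least 2-fold higher, was within the background range on both WT arrays. Fibroblast and collagen genes (median -0.16), endothelial genes (-0.51) and cell cycle genes (-0.14) did not stand apart from random lists, though the endothelial list did with averaged probe sets (-0.56), and 0 of 29 cell cycle genes differed 2-fold.

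Over all 6197 genes above the level filter, 341 were at least 2-fold higher and 511 at least 2-fold lower in the WT RU486 pool, and 8 and 101 differed at least 8-fold. Among the genes above the level filter, to which the rankings of single genes are limited in all comparisons, the largest positive differences were those of Lyve1, a receptor of lymphatic endothelium and tissue macrophages (4.40), Igkv8-30 (3.89), the Wnt modulator gene Dkk2 (3.55), Cx3cr1 (3.51), the macrophage lectin gene Siglec1 (3.51), Ighm (3.35), Cd83 (3.11), Dmpk (3.02), Fcrls (2.97), Csf1, the gene of macrophage colony-stimulating factor (2.92), F13a1 (2.89) and Ccl12 (2.88). Those with the largest negative differences were the gap junction gene Gjb2 (-6.59), the serum amyloid genes Saa1 (-6.39) and Saa2 (-5.99), S100a14 (-6.37), Elf5 (-5.89), Wap (-5.75), the nucleoside transporter gene Slc28a3 (-5.70), Krt6a (-5.69), Glycam1 (-5.52), the collagenase gene Mmp13 (-5.20), the casein gene Csn1s1 (-5.10) and the mucin gene Muc15 (-5.07). Of the 35 lists, 6 stood higher and 12 lower than 99% of random lists matched on expression. If the lists were random draws of genes, 0.7 would do so. The genes of these lists are not independent, so 0.7 is not their chance rate. Among 221 genes that differed at least 2-fold and had a second probe set at or above the filter level, that probe set had the same sign for 218. It was also at least 2-fold different for 175 of them. Dimmer probe sets were left out of this count. S100a14 and Krt6a were within the background range under RU486, at signals of 1.8 and 9.7. The Wnt and the stem and progenitor lists no longer stood apart when a gene's probe sets were averaged (medians of -0.33 at percentile 2.42 and -0.33 at percentile 2.56). With genes above the median level only, the neutrophil median was -2.46 and the Wnt median -0.79. With list means, the mesenchymal value was 0.48, the stem and progenitor value -0.81 and the Wnt value -0.28, the last no longer apart.

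The second comparison asked the same of PAX8PPARg mice. Here the RU486 pool had higher levels of keratinized epithelial genes and lower levels of adipocyte and lymphocyte genes. The PAX8PPARg placebo array was the highest of the 4 for 19 of 19 adipocyte, 11 of 13 B and plasma cell and 13 of 17 T and NK cell genes. A difference of that placebo pool therefore cannot be told from an effect of RU486 on them. Under RU486 the adipocyte median of PAX8PPARg minus WT was -0.34. Of 22 squamous and keratinized genes, 20 were at least 2-fold higher, with a median of 3.29. That median lies between Sprr2h and Casp14, both within the background range on the PAX8PPARg placebo array (3.4 and 1.1), so its size is not exact. Krt6a read 48.6 under placebo and 1890 under RU486, Krt16 read 9.7 and 588, and the calmodulin-like gene Calml3 read 23.9 and 633. All 19 adipocyte genes were at least 2-fold lower, with a median of -3.53, among them the adiponectin gene Adipoq (4509 under placebo and 123 under RU486), the leptin gene Lep (923 and 23.8, the latter within the background range) and Retn (1371 and 44.2).

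B and plasma cell genes had a median of -3.12 in PAX8PPARg, with 12 of 13 at least 2-fold lower, including the B cell receptor genes Cd79a (-3.85) and Cd79b (-3.72), the coactivator gene Pou2af1 (-3.86) and Jchain, which links antibody chains (-3.27). T and NK cell genes had a median of -1.91, with 13 of 17 at least 2-fold lower, including Cd3d (-3.60), Cd5 (-2.91) and the chemokine gene Ccl5 (-3.15). Cd79a, Cd79b, Pou2af1, Cd3d and Cd5 were within the background range on the PAX8PPARg RU486 array. Brown adipocyte genes had a median of -1.07, with Cox8b at -2.95, endothelial genes of -0.81, with Vwf at -1.96 and Kdr at -1.76, MHC class II genes of -0.63, with H2-Oa at -1.67, and PPARd and PPARa targets of -0.51, with Ehhadh at -1.15. Progesterone signalling genes were lower as a list, with a median of -0.95, though 3 of 13 were at least 2-fold higher and 6 at least 2-fold lower. Tnfsf11 had the largest difference of that list (-4.61, and -2.37 for its second probe set), followed by Cited1, a coactivator of estrogen receptor (-3.85), Stat5a (-1.86) and Pgr (-1.29). The median is the value of Fkbp5, which is also on the glucocorticoid receptor target list. The PAX8PPARg placebo array was the highest of the 4 for 5 of the 13 genes, among them Tnfsf11, Cited1, Pgr and Fkbp5. For these, a difference of that placebo pool cannot be told from an effect of RU486.

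On the higher side in PAX8PPARg stood neutrophil and myeloid granule genes (median 1.87, 11 of 16 at least 2-fold higher), with Mmp9 at 3.27, S100a8 at 3.15 and S100a9 at 2.76, and hair genes (1.35, 15 of 19), with Tchh at 5.06 and Krt27 at 4.89. The hair median is the value of Krt84, which was within the background range on both PAX8PPARg arrays, so its size is not exact. Mmp8, counted among the 11 neutrophil genes, was also within that range on both arrays. Basal and myoepithelial genes had a median of 1.14, with Krt14 at 2.57, Krt5 at 2.26 and Krt15 at 1.91, and 4 of 17 were at least 2-fold lower. Hypoxia and glycolysis genes had a median of 0.98, with Ndrg1 at 1.78, the glucose transporter gene Slc2a1 at 1.43 and Vegfa at 1.43. Wnt targets had a median of 0.66, with Notum at 5.66, Wif1 at signals of 235.4 under placebo and 1815 under RU486, and Axin2 at 1.70 (Notum read 2.1 under placebo, within the background range), and stem and progenitor genes of 0.49, with Bcl11a at 2.84 and Lgr6 at 2.20. Cell cycle genes had a median of 0.50, but 1 of 29, Birc5, differed by at least 2-fold (1.11). Ribosomal protein genes had a median of 1.15, with Rplp0 at 1.29 and Rpl19 at 1.22, which became 0.19 under quantile normalization and no longer stood apart (percentile 98.96). The luminal epithelial list (0.40), the milk protein list (0.06) and the macrophage list (0.06) did not stand apart.

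In all, 313 genes were at least 2-fold higher and 316 at least 2-fold lower in the PAX8PPARg RU486 pool, and 20 and 24 differed at least 8-fold. Without centring of the arrays, the split was 230 higher and 414 lower, and the median of the 6197 genes lay at -0.08 in place of 0.05. Among genes above the level filter, the largest positive differences were those of the stromelysin gene Mmp10 (6.54), Mmp13 (5.93), the serum amyloid genes Saa3 (5.87) and Saa1 (3.63), the chromatin protein gene Hmga2 (5.69), Krt79 (5.10), Krt6a (5.02), the troponin gene Tnnt2 (5.00), the water channel gene Aqp3 (4.85), the epidermal genes Dmkn (4.10) and Asprv1 (4.01), and Ptgs2, the gene of inducible cyclooxygenase (3.64). Mmp10 and Mmp13 were within the background range on the PAX8PPARg placebo array. The largest negative differences among them were those of the cytochrome gene Cyp2e1 (-5.36), Adipoq (-4.90), Tnfsf11 (-4.61), Pcp4 (-4.30), Cited1 (-3.85), the fatty acid transporter gene Cd36 (-3.74), the defensin gene Defb1 (-3.71), Nnat (-3.55), Fgg (-3.54), the triglyceride synthesis gene Dgat2 (-3.53), Acss2 (-3.42) and Muc15 (-3.41). A total of 9 lists stood higher and 8 lower than 99% of random lists. The basal list (mean 0.50) and the PPARd and PPARa list (mean -0.45) no longer stood apart when the mean replaced the median, and the stem and progenitor list did not with genes above the median level only (0.34).

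**Figure D1:**
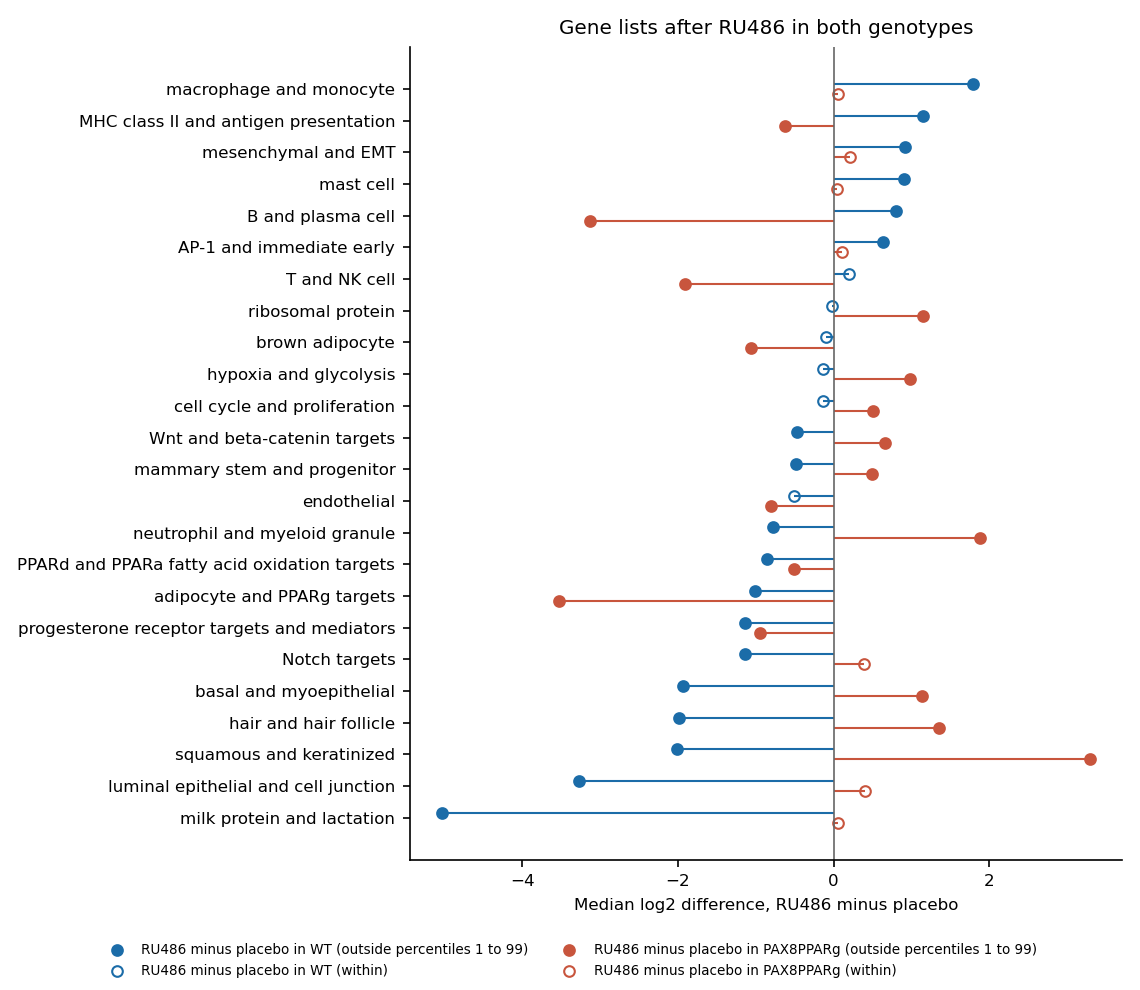
Median log2 difference between RU486 and placebo (x axis) for the 24 gene lists that stood apart in at least 1 genotype, with 1 row per list, WT in blue and PAX8PPARg in red. Filled circles lie outside percentiles 1 to 99 of matched random lists and open circles within them. Squamous genes lie at -2.02 in WT and 3.29 in PAX8PPARg, sizes that rest on signals within the background range and are not exact. Progesterone signalling genes lie at -1.13 and -0.95.

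The pair of RU486 differences, which share no array, was then set side by side. Few gene programmes pointed the same way in both genotypes, and several pointed in opposite ways. Lists that stood lower in both were those of progesterone signalling, adipocytes, and PPARd and PPARa targets. Lists that stood apart in opposite directions were those of basal, squamous, hair, stem and progenitor, Wnt target, neutrophil, B and plasma cell, and MHC class II genes. Of these, the calls of the basal, the stem and progenitor, the Wnt, and the PPARd and PPARa lists were lost in at least 1 genotype under an alternative given above. Across genes the differences were nearly unrelated (Pearson r = -0.09, Spearman rho = 0.02 over 6197 genes, which are not independent replicates), and 49.8% of genes had the same sign.

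At least 2-fold lower in both genotypes were 87 genes, where independent lists of these sizes would share 26.1. They included Defb1 (-4.35 in WT and -3.71 in PAX8PPARg), Muc15 (-5.07 and -3.41), Glycam1 (-5.52 and -2.77), Tnfsf11 (-2.49 and -4.61), Pcp4 (-2.47 and -4.30), Stat5a (-2.59 and -1.86), Cited1 (-1.13 and -3.85), Gpd1 (-2.63 and -2.92), Lpl (-2.11 and -3.03), Acss2 (-2.46 and -3.42) and Cyp2e1 (-2.02 and -5.36). A further 13 were at least 2-fold higher in both (17.2 for independent lists), among them Fn1 (1.39 and 1.64), Itga5 (1.44 and 1.05) and the scavenger receptor gene Msr1 (2.58 and 1.28). Opposite directions were taken by 47 genes that were higher in WT and lower in PAX8PPARg (17.4 for independent lists) and by 87 that were lower in WT and higher in PAX8PPARg (25.8). Opposite directions thus exceeded independent lists too, so the excess of genes lower in both does not by itself show a shared response to RU486. Of the genes named as lower in both, all but Muc15, Glycam1 and Stat5a had their highest signal on the PAX8PPARg placebo array.

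**Figure D2:**
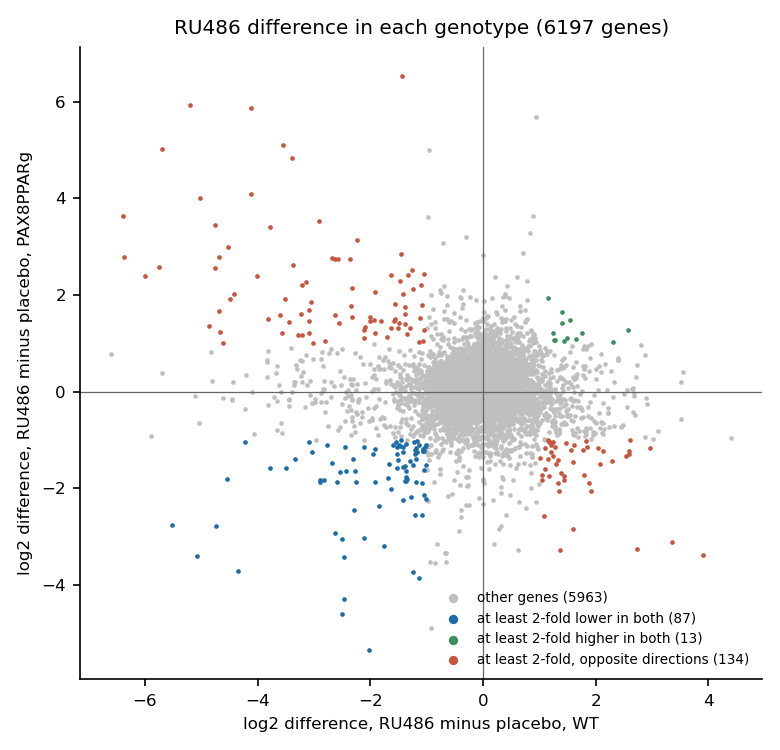
Log2 difference between RU486 and placebo in WT (x axis) and in PAX8PPARg (y axis), with 1 point for each of 6197 genes. Coloured points differ at least 2-fold in both genotypes: 87 genes were lower in both, 13 higher in both and 134 in opposite directions.

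The difference between the RU486 effects of the genotypes (PAX8PPARg minus WT) was at least 2-fold positive for 722 genes and at least 2-fold negative for 620, with a median of 0.14 over all genes that was 0.00 without centring. The larger side depended on the scaling, with 624 positive and 668 negative under quantile normalization and 584 and 746 without centring. On the positive side stood squamous (median 5.10), milk protein (4.37), luminal (3.77), hair (3.61), basal (2.48) and neutrophil genes (2.24), and then hypoxia (1.23), stem and progenitor (1.21), Notch (1.16), ribosomal protein (1.16), Wnt (1.03) and cell cycle genes (0.64). On the negative side stood B and plasma cell (-3.79), adipocyte (-2.60), macrophage (-2.04), T and NK cell (-1.66), MHC class II (-1.64), mast cell (-1.27) and AP-1 genes (-0.37), and estrogen signalling genes (-0.31), with Esr1 at -3.87 and the pioneer factor gene Foxa1 at -2.22. The single genes above the level filter with the largest values were Mmp13 (11.13), Krt6a (10.70), Saa1 (10.02), Saa3 (9.99), S100a14 (9.15) and Asprv1 (9.03), and, negative, Igkv8-30 (-7.29), Ighm (-6.47), Igk (-5.99), Lyve1 (-5.37), Jchain (-4.64) and Ear3 (-4.44). The values of Mmp13 rest on a signal within the background range on the PAX8PPARg placebo array. Those of Krt6a and S100a14 do on the WT RU486 array, and those of Esr1 and Foxa1 on the PAX8PPARg RU486 array. The sizes and ranks of these genes are not exact. The squamous median lies between Krt10 and Sprr2h. Sprr2h was within the background range on the WT RU486 (6.7) and PAX8PPARg placebo (3.4) arrays, so the size of that median is not exact. Igk and Ighm depended on the probe set, from -5.99 to 0.21 and from -7.83 to 0.21. Under quantile normalization the estrogen signalling list lay at percentile 1.90, within the random range, the ribosomal median was 0.33 and the Wnt median 0.66. With genes above the median level only, the estrogen signalling list had a median of 0.09, so its direction was not settled. In that setting the adipocyte median was -1.35, the neutrophil median 4.62 and the AP-1 median -0.91. The AP-1 list no longer stood apart with averaged probe sets (-0.29) or with its mean (-0.30), nor did the Notch and cell cycle lists with theirs (1.01 and 0.57), and the mast cell mean was -0.84.

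The third comparison set PAX8PPARg against WT tumours under placebo. The PAX8PPARg pool had higher levels of adipocyte, B cell and T cell genes, and lower levels of milk protein and keratinized genes. All 13 B and plasma cell genes but 2 were at least 2-fold higher, with a median of 2.97 and with Cd79b at a signal of 21.2 in WT and 627 in PAX8PPARg. T and NK cell genes had a median of 1.67, with 10 of 17 at least 2-fold higher, among them Cd3d (2.83), Cd3g (2.33) and Ccl5 (2.64). Adipocyte genes had a median of 2.17, with 15 of 19 at least 2-fold higher, among them Adipoq (3.52), Lep (3.46) and Dgat2 (3.27), and the Pparg probe set lay 2.29 higher.

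Milk protein genes were lower in the PAX8PPARg placebo pool, with 14 of 15 at least 2-fold lower and a median of -2.02. Wap read 9419 in WT and 34.2 in PAX8PPARg, and Lalba read 2456 and 42.0. Squamous genes had a median of -1.88 (19 of 22 at least 2-fold lower), with Krt16 at -5.14 and Krt6a at -4.55. That median lies between Casp14 and Sprr2d, both within the background range on the PAX8PPARg placebo array (1.1 and 2.7), so its size is not exact. Hair genes had a median of -2.38 (17 of 19 at least 2-fold lower), with Krt27 at -5.92. Neutrophil genes had a median of -1.63, with Il1b at -3.32 and S100a8 at -3.11, and skeletal muscle genes of -1.36, with the myosin gene Myh4 at -3.66 and Acta1 at -2.88. Matrix genes were lower too, both the fibroblast and collagen list (-0.73, with Col12a1 at -3.76) and the mesenchymal list (-0.64, with Tnc at -3.07). Smaller negative medians were those of hypoxia (-0.70, with Adm at -1.62), Wnt (-0.59, with Axin2 at -1.31) and stem and progenitor genes (-0.55, with Cd44 at -2.15).

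Interferon response genes were higher in the PAX8PPARg placebo pool (median 0.84, 7 of 22 at least 2-fold higher), with Usp18 at 1.99 and Cxcl9 at 1.68, as were endothelial genes (0.65), with Vwf at 1.40 and Kdr at 1.14, and MHC class II genes (0.27), with H2-Oa at 1.84. Hormone-sensing luminal genes had a median of 0.28, with Cited1 at 2.72, Pgr at 2.05, Foxa1 at 1.95 and Cxcl12 at 1.83, while Esr1 differed by 1.45. With genes above the median level only, that median was -0.07, so the list's direction was not settled. The luminal epithelial list had a median of -0.42, but 1 of its 18 genes, Krt7, differed 2-fold (-1.07), and under quantile normalization the median was -0.22 at percentile 1.16, no longer apart, as with averaged probe sets (-0.33) and with the list mean (-0.29). The MHC class II median was 0.46 under quantile normalization, and the list did not stand apart by its mean (0.43), nor did the Wnt (-0.57) and the stem and progenitor lists (-0.59). With genes above the median level only, the adipocyte median was 1.28, the neutrophil median -2.92 and the skeletal muscle median -2.24. The milk protein mean was -3.11 and the mesenchymal mean -1.08.

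Altogether 117 genes were at least 2-fold higher and 272 at least 2-fold lower in the PAX8PPARg placebo pool, and 7 and 24 differed at least 8-fold. The split depended on the scaling, with 169 higher and 220 lower under quantile normalization and 182 higher and 192 lower without centring. The median of the 6197 genes lay at -0.19 with centring and at 0.00 without, so the differences here are relative to a scale that is uncertain by that amount. Among genes above the level filter, the largest positive differences were those of the immunoglobulin genes Igkv8-30 (4.68), Igk (4.17, with 4 probe sets from -0.13 to 4.17), Jchain (3.54) and Igha (2.94), Adipoq (3.52), Dgat2 (3.27), Cyp2e1 (3.04), the T cell receptor gene Trav9d-3 (2.80, with 5 probe sets from -0.28 to 2.80), Rbp4 (2.79), Cited1 (2.72), Retnla (2.71) and 1 predicted gene. The largest negative ones among them were those of Wap (-7.74), Mmp10 (-7.33), Saa3 (-7.01), Mmp13 (-6.98), Saa1 (-6.82), Saa2 (-6.65), Hmga2 (-6.09), Ptgs2 (-4.72), Tnnt2 (-4.63), the kallikrein gene Klk8 (-4.56), Krt6a (-4.55) and the activin gene Inhba (-4.30). Mmp10 (0.5) and Mmp13 (5.4) were within the background range on the PAX8PPARg placebo array.

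The fourth comparison set PAX8PPARg against WT tumours under RU486. Epithelial genes were higher in the PAX8PPARg pool, and macrophage, mast cell and mesenchymal genes were lower. Luminal genes had a median of 3.55, with 17 of 18 at least 2-fold higher, including Krt7 (5.14) and the E-cadherin gene Cdh1 (4.15). Squamous genes had a median of 2.98 (18 of 22 at least 2-fold higher). That median lies between Krt10 and Sprr2d, the latter within the background range on the WT RU486 array (12.1), so its size is not exact. Basal genes had a median of 2.33 (10 of 17), milk protein genes of 1.62 (10 of 15), with the casein gene Csn2 at 3.88, and hair genes of 1.19 (12 of 19). Macrophage genes had a median of -1.90 (18 of 21 at least 2-fold lower), with the mannose receptor gene Mrc1 at a signal of 7957 in WT and 1023 in PAX8PPARg.

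Skeletal muscle genes had a median of -1.55 in this comparison, with Myh1 at -3.21 and Myl1 at -2.22, mast cell genes of -1.51, with Cpa3 at -2.66, MHC class II genes of -1.28, with Cd86 at -3.01, mesenchymal genes of -1.12, with Zeb2 at -3.29 and Twist1 at -1.93, B and plasma cell genes of -0.66, with Cd37 at -1.63, and AP-1 genes of -0.55, with Fos at -2.44. Positive medians were also found for the Notch list of targets, ligands and receptors (1.28, with the ligand gene Jag2 at 1.86) and for neutrophil genes (0.88, with Ltf at 3.23). So they were for ribosomal protein genes (0.85, and 0.34 under quantile normalization). Wnt targets had a median of 0.73, with Nkd1 at 2.33, from a WT signal of 5.5 within the background range. Progesterone signalling genes (0.56, with Elf5 at 3.73) and cell cycle genes (0.54, with Bub1b at 1.12) had positive medians too. The progesterone signalling list did not stand apart when probe sets were averaged (median 0.25) or with genes above the median level only (0.06), nor did the AP-1 list with averaged probe sets (-0.42). The milk protein median was 1.06 with averaged probe sets, and the neutrophil median 2.44 with genes above the median level only. In total 448 genes were at least 2-fold higher and 634 at least 2-fold lower. Among genes above the level filter, the largest positive differences were those of S100a14 (7.14), Asprv1 (6.75), Krt79 (6.34), Krt6a (6.15), Krtdap (5.91), Krt15 (5.88), Wif1 (5.51) and the glutathione transferase gene Gsta4 (5.49), and the largest negative ones those of Fcrls (-4.02), Lyve1 (-3.94), Ighm (-3.82), Efemp1 (-3.68), the monocyte receptor gene Ccr2 (-3.60), Cd83 (-3.57), Dkk2 (-3.56) and Csf1 (-3.51). S100a14, Krt6a, Krtdap and Krt15 were within the background range on the WT RU486 array and so their sizes and ranks are not exact.

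The genotype differences under placebo and under RU486, which share no array, were as weakly related across genes as the RU486 differences were (Pearson r = -0.09). Of the genes that differed at least 2-fold in both, 74 were lower in PAX8PPARg under both treatments (27.8 for independent lists) and 25 were higher (8.46), while 28 were higher under placebo and lower under RU486 (11.97) and 75 the reverse (19.7). Skeletal muscle and mesenchymal genes stood lower in PAX8PPARg under both treatments.

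**Figure D3:**
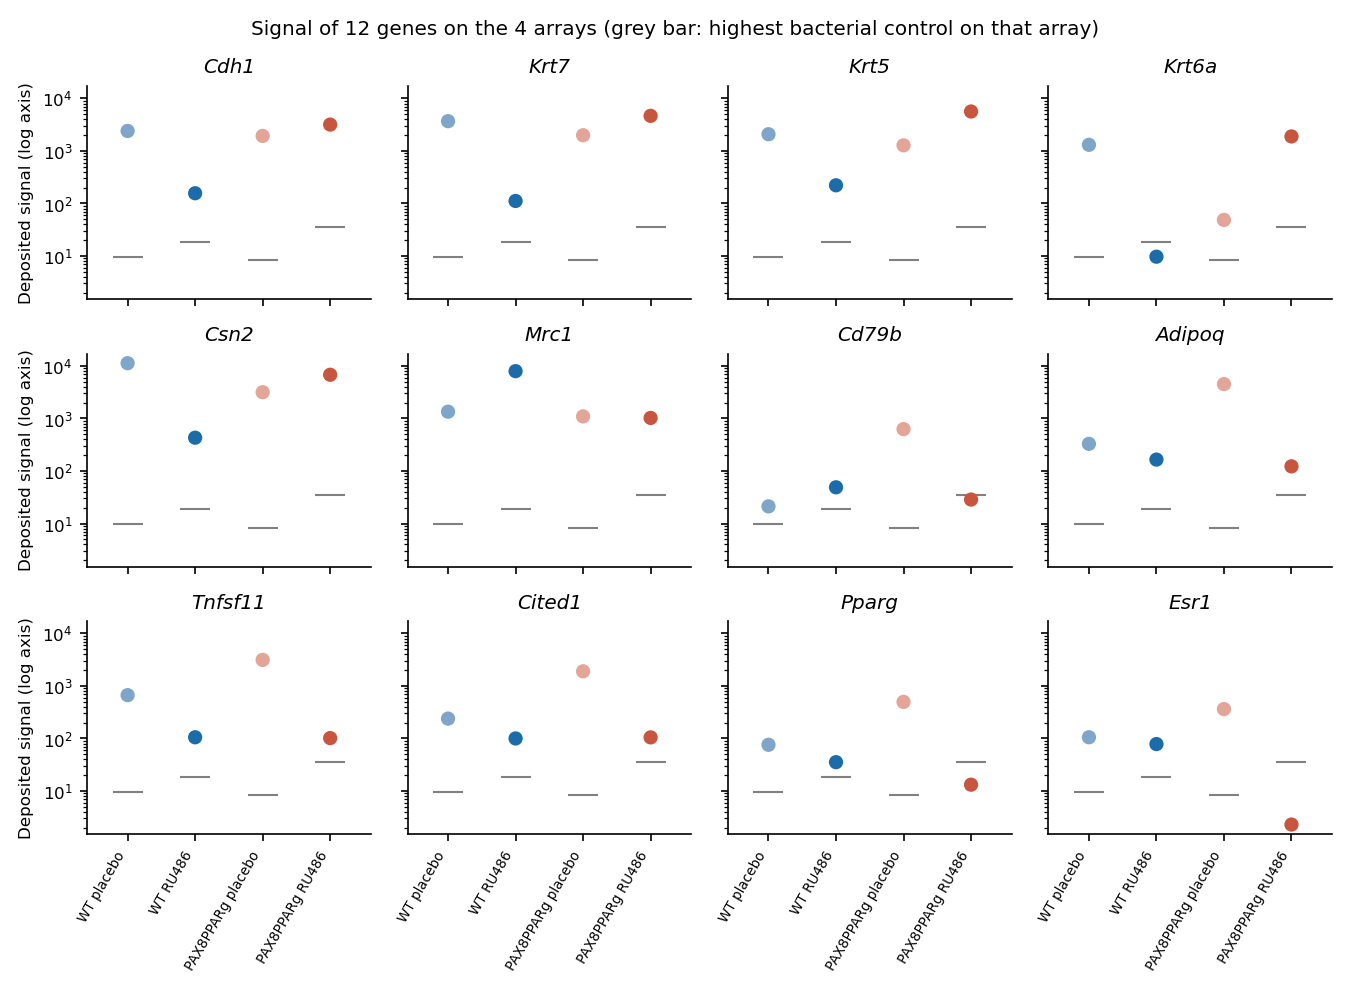
Deposited signal (log axis) of 12 genes on the 4 arrays (x axis), with 1 point per array and a grey bar at the highest bacterial control signal of that array; the genes were chosen after their values were seen. Cdh1 is lowest on the WT RU486 array (157), Adipoq is highest on the PAX8PPARg placebo array (4509), and Tnfsf11 is lower under RU486 in both genotypes (106 and 102).

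Additive models over all 4 arrays asked whether any gene shifted with RU486 in both genotypes, or with the transgene under both treatments, by more than the departure from additivity. For RU486, Defb1 had the smallest p, with an estimate of -4.03 ± 0.32 (SE) and a limma adjusted p of 0.970, followed by Gpd1 (-2.77 ± 0.29) and Cdo1 (-2.78 ± 0.31). By limma, 0 of 6197 genes passed an adjusted p of 0.05 for RU486 and 0 for PAX8PPARg, with 278 and 273 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.970 and 0.938. The diagonal split of the arrays (WT placebo with PAX8PPARg RU486 against the other pair) is the contrast of the double difference and so no neutral comparator. It also gave 0 genes, with 191 at an unadjusted p under 0.05 with treatment as the covariate and 312 with genotype. Its smallest limma adjusted p was 0.996 and 0.183, and with 1 residual degree of freedom the residual holds noise together with the interaction in the additive fits, and with the omitted factor in the diagonal fits.

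Lists that stood apart in none of the 5 comparisons were those of glucocorticoid receptor targets, aryl hydrocarbon receptor targets, housekeeping genes, red blood cells, Schwann cells, salivary gland, and PAX8 and thyroid genes. For the 20 glucocorticoid receptor targets, the median difference between RU486 and placebo was 0.01 in WT and 0.03 in PAX8PPARg, but the members went both ways, with 1 gene at least 2-fold higher and 5 lower in WT, and 5 higher and 4 lower in PAX8PPARg. The 4 lower in PAX8PPARg, named after their values were seen, were Tsc22d3 (-1.36), Zbtb16 (-1.15), Klf9 (-1.11) and Sgk1 (-1.02). The 5 higher there were Anxa1 (1.53), Cdkn1a (1.48), Mt2 (1.47), Mt1 (1.30) and Ddit4 (1.27). That list stood apart with averaged probe sets for RU486 in PAX8PPARg (-0.12), and with genes above the median level only for genotype under placebo (-0.48). The Schwann cell list did for the double difference in the same settings (-0.83 and -1.19), and the salivary gland list did by its mean for genotype under placebo (0.93). The 15 aryl hydrocarbon receptor and xenobiotic genes had medians of -0.10 and 0.45, and the 11 housekeeping genes of 0.20 and 0.58. The PAX8 and thyroid genes had a median of -0.13 for PAX8PPARg against WT under placebo and of 0.10 under RU486.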

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

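The tests of shared epithelium, of epithelial share and of fat pad and lymph node tissue were chosen only after the results were seen, while those of array scaling and of bright probe sets were written before their own results were computed.

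Luminal epithelial genes were lower in the WT RU486 pool by a median of -3.27 log2. If 1 of the 5 pooled mice had kept the level of the placebo pool, the difference could be no larger than -2.32. The 95% bootstrap interval of the median ran from -3.82 to -2.29, and 13 of 18 members lay past that bound. The interval resamples genes and holds no spread between mice or pools. The test therefore does not decide whether 1 mouse kept an epithelium-rich tumour. A lower share of epithelial cells alone would raise all other cell types alike. The macrophage median (21 genes) exceeded the endothelial median (16 genes) by 2.30 (1.96 to 3.05 in a bootstrap over genes). The other cell types were therefore not raised alike, but the fall of the luminal genes could still come wholly from a lower epithelial share. Array scaling was excluded, with a median of -3.23 at percentile 0 under quantile normalization.

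T cell, B cell and adipocyte genes were higher in the PAX8PPARg placebo pool, and fat pad and lymph node tissue in the sample is a possible source. Of 49 list members, 43 (87.8%) had their highest value on that array, against 16.02% of all genes, but the lists were picked because they were higher in that pool, so the count restates the pattern and decides nothing. A difference of the tumours themselves stays open as well, untested. Signals on the WT placebo and PAX8PPARg placebo arrays were 5680 and 9047 for Fabp4, 329 and 4509 for Adipoq, 21.2 and 627 for Cd79b, 7.0 and 310 for Ms4a1, and 8.4 and 202 for Cr2, with Ms4a1 and Cr2 within the background range in WT. The labels name no cell sort, 1 B cell, 1 T cell and 0 adipocyte genes are also in another list, and array scaling was excluded, with a smallest median of 1.59 at percentile 100 under quantile normalization.

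Ribosomal protein genes were higher on the PAX8PPARg RU486 array than under placebo, by a median of 1.15 at percentile 100, where random lists ranged from 0.21 to 0.70. Compression or stretching of bright probe sets between arrays is a possible explanation. Under quantile normalization the median was 0.19 at percentile 98.96, where random lists ranged from -0.19 to 0.17. The call ended because that scaling brings the brightest genes to a common level on all arrays, so a higher level of ribosomal protein genes in the tumours is not excluded.

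The RU486 difference had opposite directions in WT and PAX8PPARg for basal (-1.94 and 1.14), squamous (-2.02 and 3.29), stem and progenitor (-0.48 and 0.49), Wnt target (-0.47 and 0.66), B and plasma cell (0.80 and -3.12), neutrophil (-0.78 and 1.87), MHC class II (1.15 and -0.63) and hair genes (-1.99 and 1.35). The genotype difference had opposite directions under placebo and RU486 for luminal (-0.42 and 3.55), squamous (-1.88 and 2.98), milk protein (-2.02 and 1.62), Wnt target (-0.59 and 0.73), B and plasma cell (2.97 and -0.66), neutrophil (-1.63 and 0.88), MHC class II (0.27 and -1.28) and hair genes (-2.38 and 1.19). Several of these opposite directions are not settled, since a call was lost under an alternative. For RU486 these were the basal list in PAX8PPARg (mean 0.50), the stem and progenitor list in WT (-0.33 with averaged probe sets) and in PAX8PPARg (0.34 with genes above the median level only), and the Wnt list in WT (-0.33 with averaged probe sets, mean -0.28). For genotype under placebo they were the luminal list (-0.22 with quantile normalization, -0.33 with averaged probe sets, mean -0.29), the Wnt list (mean -0.57) and the MHC class II list (mean 0.43). The hair median of 1.35 is the value of Krt84, within the background range on both PAX8PPARg arrays, so its size is not exact. The squamous medians also rest on genes within the background range, as given above, and their sizes are not exact. The cause of these opposite directions was not tested, and with 1 pool per group a difference between pools cannot be told from an effect of RU486 or of the transgene.

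Among mouse control probe sets, compared on log2(signal + 16) without centring of the arrays, those of 18S ribosomal RNA were higher on the PAX8PPARg RU486 array than on the WT placebo array by 1.65, 1.74 and 1.30 log2, and that of the B2 repeat by 1.06, where the spike-in probe sets were higher by 1.28 in mean log2(signal). Those of pyruvate carboxylase were higher on the PAX8PPARg placebo array than on the WT placebo array by 2.18, 1.40, 1.998 and 1.51. The cause was not tested.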

How the results depend on the processing

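The scaling of gene lists without centring was added after the data were seen, and all other alternatives were fixed before. No paired analysis was possible because each group has 1 array, and for the same reason no array was left out.

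Without the level filter (12393 genes), the genes at least 2-fold higher and lower numbered 923 and 1097 for RU486 in WT, 1308 and 870 for RU486 in PAX8PPARg, 531 and 681 for genotype under placebo, 1341 and 1255 for genotype under RU486, and 1930 and 1504 for the double difference. With the 25% of genes of the highest mean they numbered 132 and 178, 172 and 107, 28 and 127, 179 and 263, and 333 and 222. More or fewer genes were counted in these settings, but the higher and lower counts did not move alike. With the filter, RU486 in PAX8PPARg had 313 higher and 316 lower. Genotype under RU486 had 448 higher and 634 lower, so its larger side turned without the filter. The cause was not tested. Without centring, 182 genes were higher for genotype under placebo.

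With genes above the median level only, the estrogen signalling median had the opposite sign for genotype under placebo (-0.072) and for the double difference (0.088). The cause was not tested. Of the list medians under all alternatives, 780 kept their call or their lack of one, and 27 stood apart only under the alternative. A further 21 no longer stood apart, and 2 that had stood apart took the opposite sign. Signs were compared only for lists that stood apart in the main setting. Some of the 27 changed sign as well. Examples are estrogen signalling for RU486 in PAX8PPARg (median 0.19, mean -0.78) and AP-1 for genotype under placebo (-0.13, and 0.09 with genes above the median level only). The 780 include 175 values without centring, which could not change. That setting moves all genes of a comparison by the same amount, so the percentiles stay the same. The fibroblast and collagen list gained a call for genotype under RU486 with quantile normalization (-0.47), averaged probe sets (-0.43) and genes above the median level only (-0.40). The limma calls were 0 for every fit under every alternative (16 values). Of the values of named genes, 760 stayed and 114 moved. A turn of direction was looked for only in genes that differed at least 2-fold, and 0 of those turned.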

Other observations

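The values in this part were picked after the results were seen, and none has a test between conditions. The skeletal muscle medians belong to a list fixed beforehand, which stood lower than matched random lists in both genotype comparisons.

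Skeletal muscle genes were lower in PAX8PPARg than in WT under both treatments, with medians of -1.36 and -1.55, and 14 of 24 had their highest value on the WT placebo array. Mylpf read 1477, 789, 264 and 333 on the WT placebo, WT RU486, PAX8PPARg placebo and PAX8PPARg RU486 arrays. Of 11 mast cell genes, 8 had their highest value on the WT RU486 array, where Cma1 read 466 against 137, 178 and 85.0 on the WT placebo, PAX8PPARg placebo and PAX8PPARg RU486 arrays. Kit, Hdc and Gata2 did not, and Kit was lowest there (95.1).

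Macrophage genes had their highest value on the WT RU486 array for 21 of 21 members, and mesenchymal genes for 15 of 20. Hmga2, a chromatin protein of embryonic and tumour cells, read 3671, 7073, 45.8 and 2886 in the order above, so the PAX8PPARg placebo pool stood alone. Without centring of the arrays, the transferrin receptor control probe sets differed from the WT placebo array by -1.15, -1.46 and -1.49 on the WT RU486 array and by -1.17, -1.26 and -1.15 on the PAX8PPARg placebo array.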
